A study of Arabidopsis thaliana with 8 samples.

How the data were processed

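RNA abundance was measured with 2-colour Agilent arrays in whole Arabidopsis thaliana seedlings. Per the labels, 8 arrays each held 1 mutant sample and 1 reference sample. On 4 arrays the mutant carried mutations in 6 genes of abscisic acid (ABA) receptors of the PYR/PYL family (the sextuple mutant), and on 4 in 3 genes of SnRK2 protein kinases (the triple mutant). All plants had received 10 µM ABA for 3 h. The reference was a single pool of 4 Col-0 samples, present on every array. Replicates 1 and 2 of each mutant carried Cy5 and replicates 3 and 4 carried Cy3, per the labels. Untreated plants were not analysed here, so every value compares a mutant with Col-0 after ABA, and no response to ABA was measured.

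The deposited array files hold, per the file headers, spot intensity values from Agilent Feature Extraction 9.5.1.1: mean intensity and median local background in the green and red channels, without background or dye correction in those columns. They also hold a log10 ratio of red over green that the scanner software made, per the file headers, after background subtraction, detrending, and linear and LOWESS dye normalization. Flags for spots well above background, saturated or uneven come from the same software. The deposited series table holds log2 values with no stated direction. Its columns matched the scanner software's ratio with an absolute correlation of 0.9999 across spots on every array, and by the dyes in the labels they run Col-0 over mutant on every array, with medians from -0.114 to -0.0943. Scale, centring and direction of that table could therefore all be settled from the values; 11811 of the 43803 non-control values per array are empty in it. All ratios reported here run mutant over Col-0, opposite to that table. No per-sample column was left without use in the series table (0 columns).

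Ratios were recomputed from the mean intensities in R 4.3.3 with limma 3.58.1, the data.table package (1.17.8) and jsonlite 2.0.0. Background was corrected by normexp with an offset of 50, each array was normalized by loess with control and outlying spots at weight 0, and the ratio was turned to mutant over Col-0 by the dyes in the labels. Spots of 1 probe were averaged. Of 43603 probes, 34285 were paired with a locus by RefSeq accession, 166 by another accession of the probe and 2103 by a locus name in the files. A further 7049 probes had no locus and entered no gene test, and 452 probes listed several loci. Gene symbols came from the table of assembly TAIR10.1, used for names and for the order of neighbouring genes only. It paired 236 of the 240 fixed list names with their locus, and a gene without a paired name is given by its locus. Probe coordinates are those in the files, on the build ath1:Jan2004 per the file headers. Each gene was represented by 1 probe, taking probes of a single locus first and then the brightest. Probes had to be well above background in at least 1 channel on at least 4 of 8 arrays, which left 20959 of 26632 loci. More than 1 probe passed for 6480 genes, and in 121 of them called probes of the same gene had opposite signs in the sextuple mutant. Where a gene was not well above background on any array of 1 side, its ratio is given as a bound ("at least").

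All 8 arrays entered 1 limma fit with a term for each mutant and a probe-specific dye term. Each mutant was tested against 0, the mutants were tested against each other in the same fit, and Benjamini-Hochberg adjusted p under 0.05 counted as changed. Standard errors (SE) are those of the fit; standard deviations (SD) over the 4 arrays of a mutant include the difference between the dyes. The Col-0 pool is 1 control sample, so the tests against Col-0 leave out the spread of that control. It cancels between the mutants. The p-values measure only the spread between these samples. That spread may be partly technical: arrays of the same mutant and dye were set against repeated spots of 1 array over 50 probes with 5 spots each. By the F-test at 0.05, replicates 3 and 4 of the triple mutant (F ratio 2.62) and 1 and 2 of the sextuple mutant (1.6) differed beyond repeated spots, and the other two pairs did not (1.41 and 1.34). Arrays of different mutants had F ratios of 4.4 and 3.9. The arrays of a pair of the same mutant lay on different slides. The number of arrays limits the precision. The same fit was tested on simulated data for the sextuple comparison with 20959 genes. Of 50 genes changed by a log2 of 0.25, 46 were called, and all 50 were called at each of 0.5, 1 and 2. Of 20759 unchanged genes 14 were called. The simulated data held no deviation of the shared pool and took the arrays as independent, so these counts cover neither.

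Before the data were examined, the comparisons, the alternatives, 25 gene lists and the rule for named genes were fixed. The rule takes the 9 mutated genes. Per mutant it takes the 8 largest rises and 8 largest falls with the same sign on all 4 arrays. For the difference it takes the 6 largest each way, where the arrays of the mutants do not overlap. Each list gives up to 4 members with the smallest p per mutant, plus members called in opposite directions, and up to 4 genes per mutant are named for the largest bound. The fixed lists are mutated receptors, mutated kinases, other receptors, other SnRK2 kinases, clade A PP2C phosphatases, ABF-type bZIP factors, LEA and dehydrin proteins, other ABA-related transcription factors, ABA-responsive stress metabolism, ABA biosynthesis, ABA catabolism, guard cell genes, cold and DREB regulators, photosynthesis, aquaporins, cell wall expansion, auxin response, cytokinin response, jasmonate, salicylate defence, hypoxia, cell division, root markers, seed storage and reference genes. A further 6 lists were added after the data had been seen: copper response, iron deficiency, phosphate starvation, aliphatic glucosinolates, heat shock and anthocyanin. Lists were tested with camera against all other genes at a preset correlation of 0.01, adjusted over the 22 fixed lists with at least 3 measured members. The 6 added lists were tested in the same way but adjusted over those 6 alone. Mutated genes were left out of the list tests, and seed storage had 1 measured member. The tests of the fixed lists were repeated with an estimated correlation and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes.

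Alternatives covered background correction, normalization, the filter, the choice of probe, the dye term, the variance prior, the set of arrays, the slide, the replicate number as a block, the series table and leaving out each replicate. Whether replicate numbers pair the arrays of the mutants was not settled. With the dye removed, correlations between arrays of the same number ran from -0.144 to 0.0797. The fit that removes the dye itself lowers these correlations, and arrays of the same number also shared a slide. For the pool shared by both comparisons, 20 pairs of unchanged groups were simulated with a common pool deviation, at a share of 0.25 of the replicate variance. Larger shares were not simulated.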

Results

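Transcript abundance was measured in whole seedlings grown for 15 days, 4 on plates and 11 in flasks of liquid medium, and then given 10 µM ABA for 3 h. There were 4 arrays of the sextuple mutant, in which the ABA receptor genes PYR1, PYL1, PYL2, PYL4, PYL5 and PYL8 are mutated, and 4 of the triple mutant, in which the kinase genes SNRK2.2, SNRK2.3 and SNRK2.6 are mutated. The kinases act downstream of the receptors in ABA signalling. Each array set a mutant against the same Col-0 pool. Median spot signal was 471 to 765 in green and 122 to 228 in red. Between 70.35% and 73.73% of probes per channel lay well above background. Across genes, which are not independent replicates, log2 ratios of arrays of the same mutant and dye correlated at 0.9825 to 0.9885, and those of the same mutant in opposite dyes at 0.9522 to 0.9619. Signed values are log2 ratios of mutant over Col-0, opposite in direction to the deposited series table, with the standard error of the fit and n = 4 arrays per mutant unless stated.

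The mutated genes were read on every array before anything else. In the triple mutant, SNRK2.2 was at -3.39 ± 0.041, SNRK2.3 at -4.16 ± 0.083 and SNRK2.6 at -4.75 ± 0.074, which is 10.5-fold, 17.9-fold and 27.0-fold lower than Col-0 on 4 of 4 arrays. In the sextuple mutant, PYL1 and PYL8 were not well above background on any array, at least 4.51-fold and at least 8.01-fold lower than in Col-0. PYL5 fell by 0.94 ± 0.067 there. The other 3 mutated receptor genes gave more signal in the sextuple mutant than in Col-0 on 4 of 4 arrays: PYR1 at 1.80 ± 0.034, PYL2 at 4.08 ± 0.086 and PYL4 at 3.46 ± 0.055. The alleles are not in the labels. A probe that lies outside the part a mutation removes checks nothing, and whether these 3 probes do is not known, so the label stays unchecked at these 3 genes. The probes on the build ath1:Jan2004 start at position 9929322 of chromosome 4 (PYR1), 11094874 of chromosome 2 (PYL2) and 16051026 of chromosome 2 (PYL4), and for the lower genes at 18984023 (PYL1), 1609962 (PYL5) and 21561864 (PYL8), all on chromosome 5. The kinase probes start at 18741902 of chromosome 3 (SNRK2.2), 26712594 of chromosome 5 (SNRK2.3) and 16274727 of chromosome 4 (SNRK2.6). All 6 receptor genes rose in the triple mutant, by 1.09 (PYL1) to 4.54 (PYL4). In the sextuple mutant SNRK2.6 fell by 1.52 ± 0.074 and SNRK2.2 by 0.31 ± 0.041, while SNRK2.3 was at -0.07 ± 0.083 (adjusted p = 0.437). No array was out of place by the kinase genes, PYL1, PYL5 or PYL8.

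**Figure D1:**
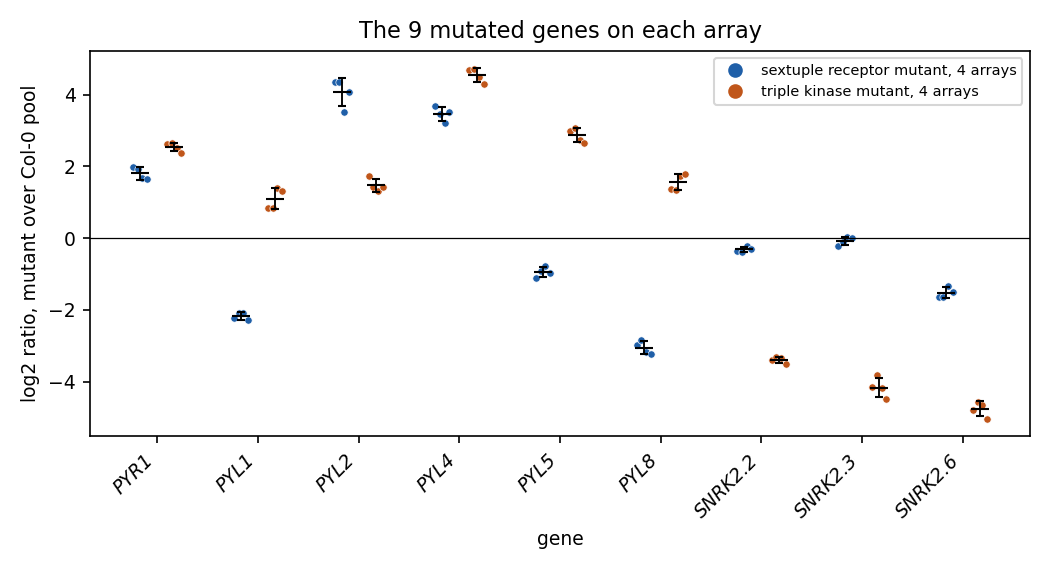
The log2 ratio of mutant over Col-0 of the 9 mutated genes, 1 point per array, with the mean and SD of the 4 arrays of each mutant. The 3 kinase genes lie between -3.39 and -4.75 on average in the triple mutant, and PYR1, PYL2 and PYL4 lie above 0 in the sextuple mutant.

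The sextuple mutant was set against Col-0 to ask which transcripts change with mutations in the 6 receptor genes in ABA-treated seedlings. Genes for water-stress proteins were far lower in it. AT3G02480, of the late embryogenesis abundant (LEA) family, was at -8.08 ± 0.175 or 270.2-fold lower, RD20, a caleosin of lipid bodies, at -7.67 ± 0.062 or 203.7-fold lower, and LEA7 at -7.46 ± 0.057. TSPO, a membrane protein related to the tryptophan-rich sensory proteins, was at -6.87 ± 0.045, and COR15A, a cryoprotective protein of the chloroplast, at -6.41 ± 0.101. Among the largest rises were AT3G01345 at 4.45 ± 0.079, AT5G24240 at 3.76 ± 0.116 and the receptor gene PYL6 at 3.598 ± 0.093. Each of these genes had its direction on 4 of 4 arrays, with adjusted p of 2.27e-10 or lower.

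The rest of the largest falls were BGLU24, a beta-glucosidase, at -6.61 ± 0.060, the LEA gene AT3G17520 at -6.44 ± 0.036 and LTP4, a lipid transfer protein, at -6.41 ± 0.111. Further large rises were CRK30, a cysteine-rich receptor-like kinase, at 3.49 ± 0.074, GASA6, a gibberellin-regulated peptide, at 3.33 ± 0.039, and AT1G66940 at 3.203 ± 0.034, beside PYL2 and PYL4. Among the 72 genes beyond 2-fold whose mutant signal was not well above background, the largest bounds were those of 4 genes: AT5G66780 was at least 28.0-fold lower, AT5G53710 at least 16.9-fold, AT5G45690 at least 14.8-fold and AT1G04560 at least 11.7-fold.

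Lists of ABA-related genes fell almost without exception in the sextuple mutant, and all counts per list adjusted over the list alone were the same as those over all genes. All 20 LEA and dehydrin genes fell (20 adjusted over the list alone), with a median of -4.60, among them COR15B at -5.60 and RD29B at -4.71 (list adjusted p = 8.96e-09). All 9 clade A PP2C phosphatases, which inhibit the SnRK2 kinases, fell (9 adjusted over the list alone), with a median of -3.35: HAI1 was at -5.97, ABI2 at -3.86 and ABI1 at -3.16 (list adjusted p = 6.12e-06). All 8 ABF-type bZIP factors fell as well (8 adjusted over the list alone), with a median of -1.69, such as ABF3 at -2.69 and ABI5 at -2.77 (list adjusted p = 0.000255). Of 21 other ABA-related transcription factors 20 fell (20 adjusted over the list alone), including RD26 at -4.77, HB7 at -4.44 and WRKY60, which lies near PYL2, at -0.83, while ABI3 stood at -0.03 (list adjusted p = 8.96e-09). In stress metabolism 20 of 21 genes fell (20 adjusted over the list alone), such as P5CS1, a proline synthesis enzyme, at -3.73 and LTP3 at -5.78, and GolS3, a galactinol synthase, rose to 0.42 (list adjusted p = 8.96e-09). These 5 lists passed with an estimated correlation too, with adjusted p from 0.0258 to 0.0351.

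Genes of ABA turnover were lower on both sides. All 5 catabolism genes fell (5 adjusted over the list alone), led by the 8'-hydroxylase CYP707A1 at -3.53, with a list adjusted p = 0.00291 and an adjusted p = 0.161 with an estimated correlation. Of 8 biosynthesis genes 6 fell (6 adjusted over the list alone), such as NCED3 at -1.75 and AAO3 at -1.58, ABA2 rose to 0.20 and NCED9 stood at -0.01. That list had an adjusted p = 0.0267, an adjusted p = 0.161 with an estimated correlation, and an adjusted p from 0.00972 to 0.0649 over 23 alternatives, of which 22 passed. All 6 cold and DREB regulators fell (6 adjusted over the list alone), including DREB2A at -2.65 and ZAT10 at -2.27 (list adjusted p = 0.00176, adjusted p = 0.0515 with an estimated correlation).

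All 10 jasmonate genes fell (10 adjusted over the list alone), with a median of -1.16: the storage proteins VSP2 and VSP1 were at -3.65 and -3.44 and the lipoxygenase LOX2 at -2.00 (list adjusted p = 0.000112, adjusted p = 0.0515 with an estimated correlation). All 10 hypoxia genes fell (10 adjusted over the list alone), with a median of -1.16. SUS1, a sucrose synthase, was at -3.43, the alcohol dehydrogenase ADH1 at -3.14 and the pyruvate decarboxylase PDC1 at -2.43 (list adjusted p = 0.000109, adjusted p = 0.0316 with an estimated correlation). Of 9 aquaporins 8 fell (8 adjusted over the list alone), such as TIP2;2 at -1.25 and PIP1A at -1.17, and TIP2;1 rose to 0.56 (list adjusted p = 0.0214, adjusted p = 0.396 with an estimated correlation). Of 18 photosynthesis genes 14 rose (14 adjusted over the list alone), among them LHCB3, of the light-harvesting antenna, at 0.91 and the Rubisco activase RCA at 0.86, and 4 did not pass: RBCS1A, LHCA2, PSBO1 and PSBP-1. The list had an adjusted p = 0.00537 and an adjusted p = 0.202 with an estimated correlation. Over 23 alternatives its adjusted p ran from 4.66e-05 to 0.196, with 21 past the threshold. In LHCA1, LHCA3, LHCB1.3, RBCS1A, RBCS2B and RBCS3B the sign followed the dye, with 2 of 4 arrays higher.

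The remaining lists did not pass in the sextuple mutant. Of 4 measured other receptors PYL6 rose, PYL7 and PYL9 fell to -0.18 and -0.45, and PYL3 was at -0.07 (3 adjusted over the list alone, list adjusted p = 0.798). Of 7 other SnRK2 kinases 5 fell (5 adjusted over the list alone), led by SNRK2.7 at -3.90 and SNRK2.9 at -2.38, SNRK2.8 rose to 0.13 and SNRK2.5 did not pass (list adjusted p = 0.122). Of 11 guard cell genes 6 fell, such as the potassium channel GORK at -2.34, 4 rose, such as MYB60 at 1.05, and SLAC1 stood at 0.01 (10 adjusted over the list alone, list adjusted p = 0.469). In cell wall expansion EXPA8 rose to 3.098, EXPA1 to 2.30, EXPA5 to 1.13 and XTH4 to 0.43, and 3 of 7 fell, including XTH24 at -0.76 (7 adjusted over the list alone, list adjusted p = 0.437). Auxin response genes went 5 up and 5 down (10 adjusted over the list alone, list adjusted p = 0.798), with SAUR15 at 1.27 and GH3.6 at -2.13. Of 5 cytokinin response regulators 4 rose, such as ARR7 at 0.82, and ARR4 was at -0.02 (4 adjusted over the list alone, list adjusted p = 0.0754, and from 0.047 to 0.139 over 23 alternatives, with 1 past the threshold). In salicylate defence 4 of 5 fell, such as WRKY70 at -1.18, and PAD4 rose to 0.49 (5 adjusted over the list alone, list adjusted p = 0.196). In cell division 4 of 5 rose, such as CYCB1;1 at 0.35, and CDKB1;1 was at 0.05 (4 adjusted over the list alone, list adjusted p = 0.149). Root markers went 4 up, such as SCR at 0.63, and 3 down, such as EXPA7 at -1.04 (7 adjusted over the list alone, list adjusted p = 0.798). Of 9 seed storage genes CRA1 alone was measured, at least 1.48-fold lower (1 adjusted over the list alone). Of 7 reference genes 4 fell, UBQ10 at -1.44, AT2G28390 at -0.44, ACT8 at -0.24 and PP2AA3 at -0.13, and 3 did not pass (4 adjusted over the list alone, list adjusted p = 0.384). PP2AA3 turned to 0.04 under the scanner software's normalization, and the median of the reference list turned from -0.13 to 0.03. For the other receptors the mean of 0.72 opposed the median of -0.12 and the test, for auxin response the median of 0.002 opposed the mean of -0.32 and the test, and for root markers the mean of -0.02 opposed the median of 0.25 and the test.

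Over all genes, 17171 of 20959 (81.93%) passed in the sextuple mutant, 8513 higher and 8658 lower, with a median absolute log2 ratio of 0.30 and a median residual SD of 0.07. Beyond 2-fold there were 2355 genes, 475 higher and 1880 lower. At 16-fold or more, 79 genes were lower and 2 were higher, AT3G01345 and PYL2. With the scanner software's normalization 10700 genes were higher and 6940 lower, and beyond 2-fold 3777 genes passed, 1574 higher and 2203 lower (1496 and 2154 in the series table), where the background step differs as well. With only the normalization changed, 749 were higher and 1683 lower by median centring and 805 and 1571 by quantile normalization. The median of all genes moved from -0.003 to 0.13, against 0.133 in the series table, 0.119 with quantile normalization and 0.0778 with median centring. Relative to that median, the photosynthesis list stood at 0.51 here and at 0.23 under the scanner software's normalization.

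**Figure D2:**
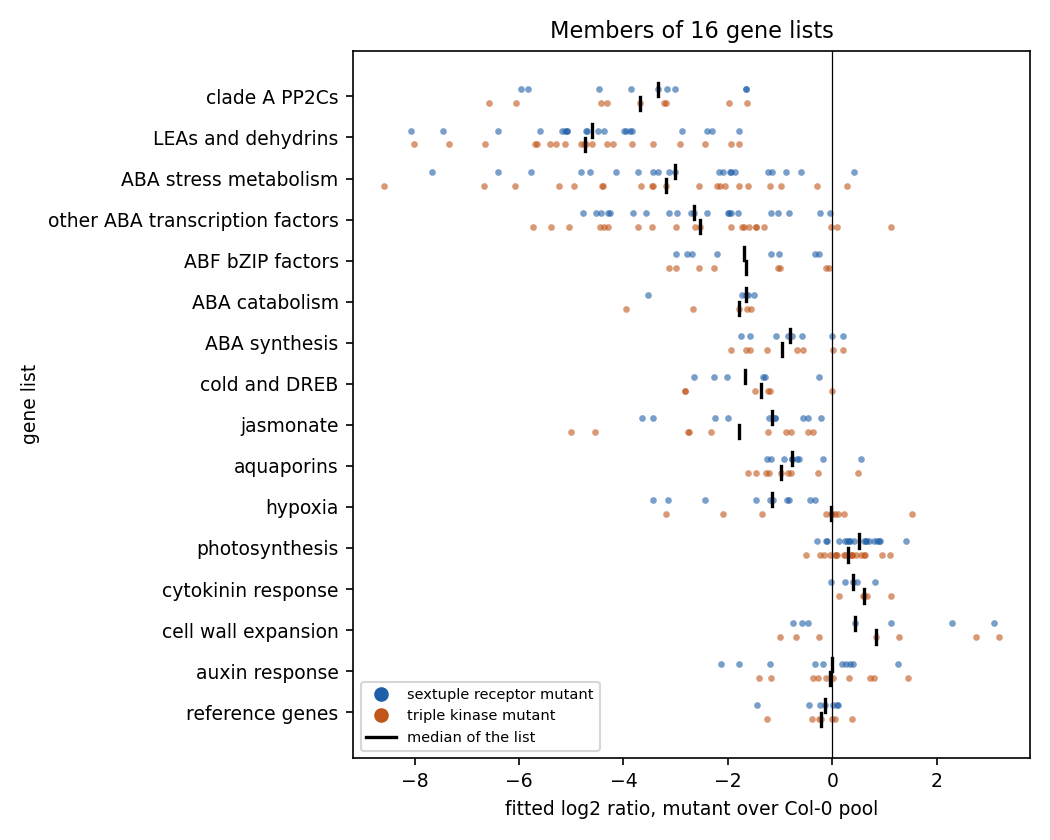
Fitted log2 ratios of mutant over Col-0 of the members of 16 gene lists, 1 point per gene and mutant, with the median of each list as a bar. LEA and dehydrin genes lie lowest, with medians of -4.60 and -4.73, and the median of the reference genes lies at -0.13 and -0.21 here but turns to 0.03 in the sextuple mutant under the scanner software's normalization and to 0.12 in the triple mutant under median centring, as hypoxia in the triple mutant turns from -0.02 to 0.13 and auxin response from -0.05 to 0.02 under the scanner software's.

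The triple mutant was set against Col-0 to ask which transcripts change with mutations in the 3 kinase genes in the same treatment. RD20 was at -8.59 ± 0.062 or 384.3-fold lower, AT3G02480 at -8.02 ± 0.175 with an SD of 0.89 over the arrays, and TSPO and LEA7 both at -7.34, all 4 of them also among the 8 largest falls of the sextuple mutant. The receptor gene PYL6 was the highest, at 5.72 ± 0.093 or 52.9-fold, followed by AT4G21870 at 4.77 ± 0.034, PYL4 and GSTF14, a glutathione transferase, at 4.51 ± 0.075. All of these held on 4 of 4 arrays, with adjusted p of 1.37e-11 or lower.

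Other large falls were AT5G15500 at -7.04 ± 0.057, AT3G03341 at -6.74 ± 0.030, AT3G17520 at -6.73 ± 0.036 and LTP4 at -6.68 ± 0.111. CRK30 rose to 4.20 ± 0.074, AT1G27020 to 3.84 ± 0.033, AT3G20380 to 3.79 ± 0.078 and IMS2, an enzyme of methionine chain elongation in glucosinolate synthesis, to 3.54 ± 0.029. BGLU24 was at least 110.9-fold lower, MYB121 at least 47.9-fold, AT5G66780 at least 26.9-fold and the ubiquitin ligase PUB19 at least 19.02-fold, each with a mutant signal not well above background.

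In the triple mutant all 20 LEA and dehydrin genes fell (20 adjusted over the list alone), with a median of -4.73 (list adjusted p = 8.19e-09), and all 9 PP2C genes fell (9 adjusted over the list alone), with a median of -3.68 (list adjusted p = 4e-06). HAI1 was at -6.58, ABI2 at -4.31 and PP2CA at -3.68. Of 21 stress metabolism genes 20 fell (20 adjusted over the list alone), such as P5CS1 at -5.23, and GolS3 rose to 0.28 (list adjusted p = 7.81e-09). Of 21 other transcription factors 18 fell (18 adjusted over the list alone), including HB7 at -5.74 and RD26 at -5.39. WRKY18 rose to 1.12 and WRKY60, near PYL2, to 0.10 with 2 of 4 arrays higher, and ABI3 was at -0.02 (list adjusted p = 8.75e-07). These 4 lists also passed with an estimated correlation, with adjusted p from 0.0243 to 0.0476. Members not well above background stand at their fitted value in these medians, and at their bounds the median of the other transcription factors was -2.53 in place of -2.54, while those of the PP2C, LEA and stress metabolism lists did not move.

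Of 8 ABF-type factors 7 fell in the triple mutant (7 adjusted over the list alone), such as GBF3 at -3.12 and ABF2 at -2.27, and EEL stood at -0.06 (list adjusted p = 0.000998, adjusted p = 0.0537 with an estimated correlation). All 5 catabolism genes fell (5 adjusted over the list alone), including CYP707A1 at -3.96 and CYP707A2 at -2.67 (list adjusted p = 0.00243, adjusted p = 0.144 with an estimated correlation). Of 8 biosynthesis genes 6 fell (6 adjusted over the list alone), such as NCED3 at -1.94 and ABA1 at -1.25, NCED9 rose to 0.20 and ABA2 was at 0.02 (list adjusted p = 0.0196, adjusted p = 0.144 with an estimated correlation). Of 6 cold and DREB regulators 5 fell (5 adjusted over the list alone), such as CBF3 and DREB2A, both at -2.81, and CBF2 was at -0.01 (list adjusted p = 0.00601, adjusted p = 0.0807 with an estimated correlation). All 10 jasmonate genes fell (10 adjusted over the list alone), with VSP2 at -5.01, VSP1 at -4.55 and the defensin PDF1.2 at -2.76 (list adjusted p = 3.8e-05, adjusted p = 0.0537 with an estimated correlation). Of 9 aquaporins 8 fell (8 adjusted over the list alone), such as TIP2;2 at -1.61, and TIP2;1 rose to 0.50 (list adjusted p = 0.00861, adjusted p = 0.426 with an estimated correlation). All 5 cytokinin response regulators rose (5 adjusted over the list alone), led by ARR7 at 1.12 and ARR15 at 0.66 (list adjusted p = 0.0233, adjusted p = 0.144 with an estimated correlation). Over 23 alternatives the adjusted p of the cytokinin list ran from 0.0114 to 0.0541, and without a dye term it missed the threshold.

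The other lists did not pass in the triple mutant. Of 10 hypoxia genes 4 fell, SUS1 at -3.18, ADH1 at -2.09, PDC1 at -1.35 and SUS4 at -0.11, and 3 rose, HRE1 at 1.54, HB1 at 0.23 and PCO1 at 0.11 (7 adjusted over the list alone, list adjusted p = 0.65). Of 18 photosynthesis genes 12 rose, such as LHCB3 at 0.60, and RBCS1A and LHCA2 fell to -0.15 and -0.49 (14 adjusted over the list alone, list adjusted p = 0.106, and from 0.00687 to 0.599 over 23 alternatives, with 4 past the threshold). With median centring 16 of the 18 rose and 0 fell, and the median went from 0.30 to 0.62, while 11 rose and 0 fell under the scanner software's normalization. PYL6 rose, PYL9 and PYL7 fell to -0.38 and -0.21, and PYL3 was at 0.05 (3 adjusted over the list alone, list adjusted p = 0.945). Of 7 other SnRK2 kinases 4 fell, such as SNRK2.7 at -3.86, and SNRK2.5 rose to 0.18 (5 adjusted over the list alone, list adjusted p = 0.106). Of 11 guard cell genes 6 fell, such as GORK at -2.57, and 4 rose, such as MYB60 at 1.19 (10 adjusted over the list alone, list adjusted p = 0.579). In cell wall expansion 4 rose, led by EXPA8 at 3.19 and EXPA1 at 2.75, and 3 fell, such as XTH24 at -1.01 (7 adjusted over the list alone, list adjusted p = 0.538). Of 10 auxin response genes 4 rose, such as SAUR15 at 1.46, and 5 fell, such as GH3.6 at -1.40 (9 adjusted over the list alone, list adjusted p = 0.945). In salicylate defence PAD4 rose to 0.93 and 3 of 5 fell, PR2 at -0.75, WRKY70 at -0.58 and NIMIN1 at -0.35 (4 adjusted over the list alone, list adjusted p = 0.586). In cell division 3 of 5 rose, KN at 0.08 on 3 of 4 arrays, CYCB1;2 at 0.28 and CYCB1;1 at 0.22, and CDKB1;1 was at -0.12, with 2 of 4 arrays lower, but at 0.03 under the scanner software's normalization (4 adjusted over the list alone, list adjusted p = 0.586). KN turned to -0.01 with the mean of all probes. Of 7 root markers 3 rose and 3 fell over all genes, SCR, SHR and PLT1 against EXPA7, CASP1 and COBL9, and 7 passed adjusted over the list alone (list adjusted p = 0.921). CRA1, of seed storage, was at least 1.603-fold lower (1 adjusted over the list alone). Of the reference genes ACT2 rose to 0.38, UBQ10, AT2G28390 and PP2AA3 fell, and the median of -0.21 turned to 0.12 under median centring (4 adjusted over the list alone, list adjusted p = 0.591). For the other receptors the mean of 1.29 opposed the median of -0.08 and the test, and the median turned to 0.07 under the scanner software's normalization. For root markers the median of 0.12 opposed the mean of -0.20 and the test.

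Over all genes 17551 (83.74%) passed in the triple mutant, 9090 higher and 8461 lower, and 2661 of them beyond 2-fold, 690 higher and 1971 lower. At 16-fold or more 115 genes were lower and 5 were higher: PYL6, AT4G21870, PYL4, GSTF14 and CRK30. With the scanner software's normalization 11165 genes were higher and 6784 lower, and beyond 2-fold 4182 genes passed, 1897 higher and 2285 lower (1781 and 2243 in the series table), against 1021 and 1721 by median centring and 1009 and 1660 by quantile normalization. The median of all genes moved from 0.02 to 0.168, against 0.165 in the series table, 0.142 with quantile normalization and 0.121 with median centring.

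Both mutants were then compared with each other, to ask how far mutations in the receptor genes and in the kinase genes go with changes in the same transcripts. RD29B at -4.71 and -4.75, ABI1 at -3.16 and -3.18 and ALDH7B4, an aldehyde dehydrogenase, at -3.44 and -3.46 were close in both, with differences of 0.04 ± 0.076, 0.02 ± 0.044 and 0.02 ± 0.038 that did not pass (adjusted p = 0.714 for RD29B). Lower beyond 2-fold in both were 1666 genes, 88.62% of those in the sextuple mutant and 84.53% of those in the triple mutant, where 176.8 would be expected from independent sets. Higher beyond 2-fold in both were 366 genes, 77.05% of those in the sextuple mutant and 53.04% of those in the triple mutant, with 15.64 expected. Passing 2-fold in opposite directions were 3 genes, CSD2, PYL1 and PYL8, of which PYL1 and PYL8 are bounds in the sextuple mutant. The log2 ratios of the mutants correlated at 0.941 across genes, which are not independent replicates. Calls were shared in direction for 15042 genes and opposite for 572. Unchanged groups simulated with a shared pool at a share of 0.25 of the replicate variance gave a correlation of at most 0.5227 and at most 14 shared calls. The share chosen sets that correlation (simulated mean 0.5021), and a larger deviation of the pool would raise both values. The counts expected from independent sets leave the shared pool out. Neither comparison therefore excludes the pool as a source of small shared changes.

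**Figure D3:**
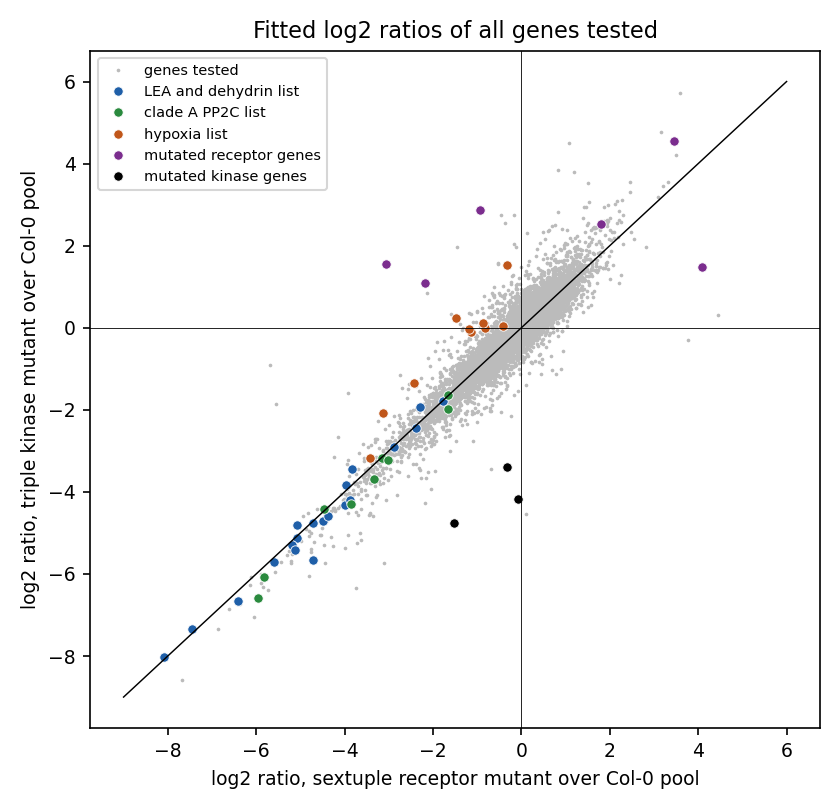
Fitted log2 ratio over Col-0 of each gene in the sextuple mutant (horizontal) and in the triple mutant (vertical), with 3 lists and the mutated genes in colour and a line of equal values. Most genes lie along the line, with a correlation of 0.941 across genes, while the 10 hypoxia genes, with a median of -1.16 against -0.02, lie above it; the triple median turns to 0.13 under the scanner software's normalization.

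The mutants also differed. MRD1 was at 0.11 ± 0.064 in the sextuple mutant and at -4.53 in the triple mutant, a difference of 4.63 ± 0.091, and AT3G01345 was higher by 4.16 ± 0.111 and AT5G24240 by 4.06 ± 0.164 in the sextuple mutant. AT2G25510 and AT2G25450, which both lie near PYL2, were lower in the sextuple mutant, with differences of -4.77 ± 0.156 and -3.70 ± 0.079. CSD2, a copper/zinc superoxide dismutase, was at -1.46 against 1.97 (difference -3.43 ± 0.049), and GSTF14 at 1.09 against 4.51 (difference -3.42 ± 0.106). Genes named for their difference had to have arrays that do not overlap between the mutants. Adjusted p of the differences was 6.03e-08 or lower. The other large differences were those of the mutated genes SNRK2.2, SNRK2.3, SNRK2.6, PYL5 and PYL8.

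The hypoxia list differed most clearly. All 10 members were lower in the sextuple than in the triple mutant (10 adjusted over the list alone), by a median of -1.03 (list adjusted p = 6.32e-10, and an adjusted p of 0.0209 with an estimated correlation). HRE1, an ethylene response factor, was at -0.33 against 1.54 (difference -1.87 ± 0.043), and the phytoglobin HB1 at -1.47 against 0.23 (difference -1.70 ± 0.038). The cysteine oxidases PCO2 and PCO1 differed by -1.16 ± 0.047 and -0.97 ± 0.046, PDC1 by -1.08 ± 0.041 and ADH1 by -1.05 ± 0.163. The adjusted p of the list ran from 8.07e-13 to 1.17e-08 over 22 alternatives, all past the threshold. Whether the difference comes from genotype or from the growth of these samples, 11 days of it in flasks, is not settled.

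**Figure D4:**
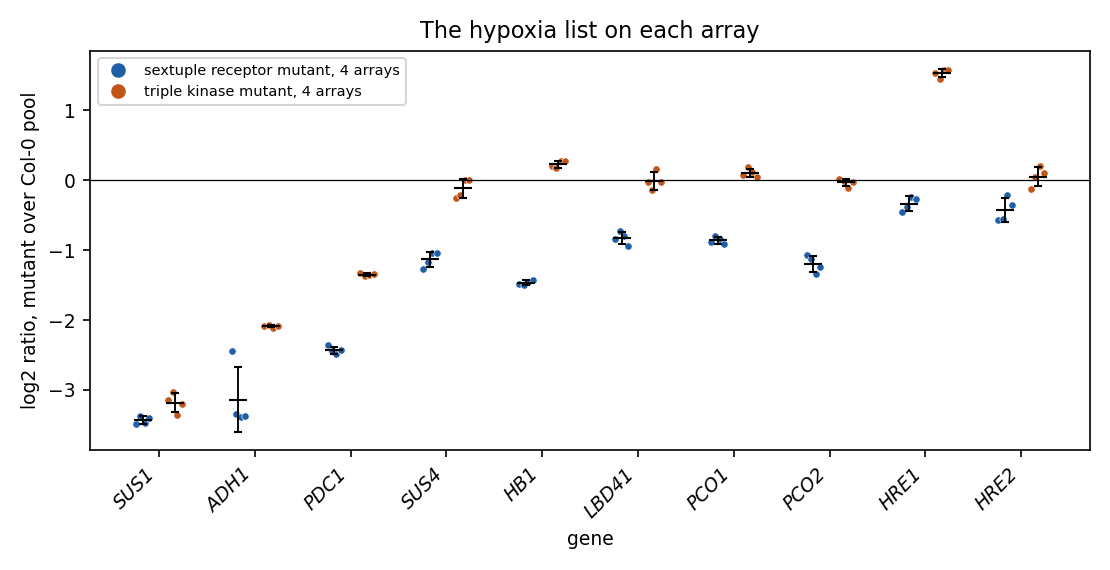
The log2 ratio of mutant over Col-0 of the 10 hypoxia genes, 1 point per array, with the mean and SD of the 4 arrays of each mutant. All 10 are lower in the sextuple mutant, with a median difference of -1.03, and ADH1 has 1 sextuple array at -2.45 apart from the rest; members near 0 in the triple mutant, such as HRE2 and LBD41, shift with the scaling, as the triple median of -0.02 turns to 0.13 under the scanner software's normalization.

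Jasmonate genes were less reduced in the sextuple mutant: 5 of 10 were higher in it than in the triple mutant, PDF1.2 by 1.66 ± 0.045, VSP2 by 1.36 ± 0.085, VSP1 by 1.11, LOX2 by 0.75 and AOS by 0.56, and JAZ5 and THI2.1 were lower (7 adjusted over the list alone, list adjusted p = 0.00434, adjusted p = 0.148 with an estimated correlation). Of 9 PP2C genes 5 were higher in the sextuple mutant (5 adjusted over the list alone), HAI1 by 0.61 ± 0.074, ABI2 by 0.45, PP2CA and HAB2 both by 0.33 and HAB1 by 0.20 (list adjusted p = 0.00434, adjusted p = 0.148 with an estimated correlation). In stress metabolism 11 of 21 were higher (12 adjusted over the list alone), such as P5CS1 by 1.51 ± 0.080 and RD20 by 0.92 ± 0.088, and 3 were lower, ERD15, DI21 and GolS2 (list adjusted p = 0.00434, adjusted p = 0.148 with an estimated correlation). Of 18 photosynthesis genes 11 were higher (11 adjusted over the list alone), such as LHCB3 by 0.31 and RCA by 0.23, and RBCS1A by 0.28 but by -0.15 under the scanner software's normalization. The count of 11 was 3 under that normalization, 2 with the series table, 4 with quantile normalization and 5 with an offset of 16, and the median difference of 0.23 was 0.09 under the scanner software's. That list had an adjusted p = 0.00434 and an adjusted p = 0.216 with an estimated correlation, and over 22 alternatives an adjusted p from 1.01e-05 to 0.149, with 20 past the threshold. Of 9 aquaporins 4 were higher (4 adjusted over the list alone), PIP2B by 0.44, TIP2;2 by 0.37, PIP2A by 0.35 and TIP1;1 by 0.16 (list adjusted p = 0.00434, adjusted p = 0.315 with an estimated correlation). Of 7 root markers 4 were higher (4 adjusted over the list alone), CASP1 by 0.45, COBL9 by 0.33, EXPA7 by 0.28 and PIN2 by 0.27 (list adjusted p = 0.0326, adjusted p = 0.148 with an estimated correlation, and from 0.0206 to 0.091 over 22 alternatives, with 20 past the threshold).

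Auxin response genes were lower in the sextuple mutant in 5 of 10 cases (5 adjusted over the list alone), with differences of -1.07 ± 0.054 for GH3.3, -0.73 for GH3.6, -0.62 for GH3.5, -0.46 for IAA29 and -0.33 for IAA19 (list adjusted p = 0.0227, adjusted p = 0.148 with an estimated correlation). All 5 cytokinin response regulators were lower (5 adjusted over the list alone), from -0.14 for ARR4 to -0.33 for ARR6 (list adjusted p = 0.0227, adjusted p = 0.148 with an estimated correlation). In salicylate defence PR5 differed by -0.67 ± 0.054, WRKY70 by -0.60 and PAD4 by -0.45, while NIMIN1 passed only when adjusted over the list alone (4 adjusted over the list alone, 3 over all genes, list adjusted p = 0.0227, adjusted p = 0.148 with an estimated correlation). Over 22 alternatives the adjusted p ran from 0.00804 to 0.108 for cytokinin response and from 0.00503 to 0.0885 for salicylate defence, with 21 past the threshold in each.

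The remaining lists did not pass the test of the difference. LEA and dehydrin genes had 1 member higher in the sextuple mutant, LTI30 by 0.94, and 1 lower, LEA14 with -0.40, while 3 were higher with an offset of 16, 5 without background correction and 6 with quantile normalization (2 adjusted over the list alone, list adjusted p = 0.478, and from 0.0274 to 0.823 over 22 alternatives, with 1 past the threshold). Among other transcription factors 7 were higher, such as HB7 by 1.303 ± 0.065, and 5 lower, such as WRKY18 with -1.36 ± 0.049 (12 adjusted over the list alone, list adjusted p = 0.614). WRKY60, near PYL2, differed by -0.93 ± 0.045. Its list had a median of 0.12 and a test upward, with a mean of -4.2e-05. Of 8 ABF-type factors 5 differed over all genes, ABF3 upward by 0.32 and ABI5, ABF4, AREB3 and EEL downward, and 6 adjusted over the list alone (list adjusted p = 0.879). In biosynthesis 4 of 8 were higher, BG1 by 0.50, ABA1 by 0.40, NCED3 by 0.19 and ABA2 by 0.18 (4 adjusted over the list alone, list adjusted p = 0.109, and from 0.0478 to 0.213 over 22 alternatives, with 1 past the threshold). In catabolism CYP707A2 was higher by 0.94 ± 0.063 and CYP707A1 by 0.43 (2 adjusted over the list alone, list adjusted p = 0.0827, and from 0.0299 to 0.152 over 22 alternatives, with 6 past the threshold). PYL6 was lower in the sextuple mutant, with a difference of -2.13 ± 0.132 (1 adjusted over the list alone, list adjusted p = 0.243 for the other receptors). SNRK2.9 differed by -1.0 and SNRK2.8 by 0.18 (2 adjusted over the list alone, list adjusted p = 0.49). Among the guard cell genes GORK and ALMT12 differed by 0.23 and 0.22 and RBOHD and MYB60 by -0.44 and -0.14 (5 adjusted over the list alone, 4 over all genes, list adjusted p = 0.884). In cold and DREB regulators CBF3 and ZAT12 differed by 0.80 and 0.21, and ZAT10 and CBF2 by -1.04 and -0.25 (5 adjusted over the list alone, 4 over all genes, list adjusted p = 0.932). The mean of the cold list, -0.04, opposed its median of 0.02 and the test, and that median turned to -0.05 under the scanner software's normalization. In cell wall expansion EXPA10 and XTH24 were higher and EXPA1, EXPA5, XTH4 and XTH22 lower (6 adjusted over the list alone, list adjusted p = 0.243). CDKB1;1, of cell division, was higher by 0.18 (1 adjusted over the list alone, list adjusted p = 0.169). ACT2 and ACT8, of the reference genes, differed by -0.30 and -0.24 (2 adjusted over the list alone, list adjusted p = 0.479). CRA1, of seed storage, passed only adjusted over the list alone (1 against 0 over all genes).

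Over all genes 7459 (35.59%) differed between the mutants, 3455 higher and 4004 lower in the sextuple mutant, and 235 of them beyond 2-fold, 87 higher and 148 lower. Beyond 2-fold the count was 613 with the scanner software's normalization, 238 higher and 375 lower, and 536 with the series table, 222 higher and 314 lower. Of the 1666 genes lower beyond 2-fold in both, 523 were lower still in the triple mutant and 244 in the sextuple mutant. Without the dye term 3944 genes differed.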

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

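The loess and dye normalization tests and the test of the genes around PYL2 were chosen only after the result was seen, as were the fits with added pool spread and with arrays of the same dye averaged; the other tests were written down before.

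Most genes passed in both mutants, 17171 and 17551 of 20959. The loess step as the whole source is argued against by median centring without it, under which 88.13% of the sextuple calls kept their direction and call, while the 89.45% kept under the scanner software's ratio decide nothing, since that ratio holds a LOWESS step of its own. With a share of 0.25 of the replicate variance added for the spread of the single Col-0 pool, 91.18% of the sextuple calls stayed, but this bounds the pool only if the replicates vary as plants do, and in 2 of the 4 pairs, arrays of the same mutant and dye did not differ beyond repeated spots by the F-test (17329 and 17714 genes passed with them averaged). Among genes under 2-fold, the sextuple log2 ratios of the slides correlated at 0.975 across genes, but both slides carried the same pool, and how high a deviation of the pool alone would bring this value was not simulated. A genotype difference in many transcripts, a deviation of the pool and the growth of these samples therefore cannot be told apart for the small changes.

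Genes that differ beyond 2-fold between the mutants were crowded on one side of PYL2: of 13 among its 200 neighbours, 12 lay at lower positions, up to 92 genes away, and PP2-A3 lay 66 genes away on the other side. Fewer were found in 99.76% of windows of that size over the genome (median 2, 95th percentile 6), and the highest count, also 13, was that of 51 windows, centred from 101 genes below PYL2 to 8 above it. AT2G24960, CLPB4, AT2G25260, AT2G25450, AT2G25510, AT2G25980, AT2G26030 and PP2-A3 were lower in the sextuple mutant and AT2G25625, TIP4;1, AT2G25964, PDF1.3 and PDF1.2b were higher. PDF1.2, of the jasmonate list and on another chromosome, was also higher in the sextuple mutant, by 1.66. PDF1.3 and PDF1.2b therefore need not mark the locus, but whether their probes and that of PDF1.2 read each other's transcripts was not tested. Of the windows around the other 8 mutated loci 0 were above the 95th percentile, and none of the 13 probes is listed for more than 1 locus (0%), which decides nothing since such probes were taken last. AT2G25625, TIP4;1, PDF1.3, PDF1.2b and PP2-A3 lay further from Col-0 in the triple mutant. Their sextuple and triple log2 ratios were -3.43 and -4.55, 0.22 and -0.84, -0.98 and -2.03, -0.91 and -2.11, and 0.48 and 2.32. AT2G25964 lay about as far in both (0.66 and -0.68). The window counts took genes that differed either way and were not repeated for those further from Col-0 in the sextuple mutant alone. A chromosome segment of another accession carried along with the PYL2 mutation is a candidate explanation for genes further from Col-0 in the sextuple mutant. How far an effect of the mutation on adjacent genes reaches was not tested, nor was a rearrangement. AT2G25510 and AT2G25450 may mark the locus. WRKY60, also near PYL2, differed by -0.93, which is under 2-fold. WRKY18, of the same list and on another chromosome, was also lower in the sextuple mutant, with a difference of -1.36. WRKY60 may therefore mark the locus but need not.

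Copper genes parted between the mutants. CSD1 and CSD2, known targets of a copper-responsive microRNA, and ZIP2 had been seen, and a direction was written down for 12 others: 9 were called, of which 88.9% went that way, with LAC13 (0.16) against it, and LAC3, LAC12 and FSD1 did not pass, so none of the laccases LAC3, LAC12 and LAC13 passed in the written direction. CSD2 differed by -3.38 and -3.48 within the slides, which argues against a single array or slide. A copper-responsive programme that differs between the mutants may account for the genes that passed, without the laccases, and whether it comes from genotype or from the growth of these samples is not settled. Copper itself was not measured.

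Of the splits of the 8 arrays into 4 and 4, 34 could be fitted. Only 1 of them, the real one, gave as many as the 7459 genes that differ between the mutants. The real split is always counted, so no smaller share was possible. That share lay under 0.05, the limit written down beforehand, but it does not exclude chance. It also holds only if the 8 arrays are independent samples, which the pairs of arrays that missed the limit of the F-test leave open. The highest other split gave 0 genes by limma, and at an unadjusted p under 0.05 it gave 1870 against 9381 for the real split. The other splits mix the mutants, so the difference between them adds to their spread.

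Single arrays stood apart from the rest of their mutant in 7 of 297 groups of 4 arrays. The limit used gives about 1 in 20 by chance where all values come from 1 distribution. These groups held both dyes without a dye correction, so their chance rate is not known. ADH1 was at -2.45 in replicate 1 of the sextuple mutant, against -3.39 to -3.34 in the rest, and VSP2 was at -3.30 in the same replicate. HB7 was at -4.29 in replicate 4 and GBF3 at -3.11 in replicate 3 of that mutant. In replicate 1 of the triple mutant AT1G27020 was at 3.96, ABF2 at -2.32 and CASP1 at -0.90.

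Between the mutants, 10 named genes were called in opposite directions with a called difference. These were HRE1 (-1.87), HB1 (-1.70), PCO1 (-0.97), WRKY18 (-1.36), WRKY60 (-0.93), CSD2 (-3.43), PYL5 (-3.80), PYL1 (-3.26), PYL8 (-4.61) and AT5G24240 (4.06), as log2 of the sextuple minus the triple mutant. The values of PYL1 and PYL8 are fitted ones, since their sextuple signal was not well above background. Of the lists, hypoxia differed (adjusted p = 6.32e-10, adjusted p = 0.0209 with an estimated correlation), with all 10 genes lower in the sextuple mutant by a median of -1.03. For hypoxia, as for the other lists, genotype and the growth of these samples were not told apart. PP2C, stress metabolism, photosynthesis, aquaporin and jasmonate genes each had an adjusted p = 0.00434, with medians from 0.21 to 0.32, and none passed with an estimated correlation (adjusted p = 0.148 with an estimated correlation for PP2C, stress metabolism and jasmonate, 0.216 for photosynthesis and 0.315 for aquaporins). Auxin, cytokinin and salicylate genes had an adjusted p = 0.0227, with medians from -0.45 to -0.21, and root markers an adjusted p = 0.0326 with a median of 0.27. These 4 did not pass either, each with an adjusted p = 0.148 with an estimated correlation.

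Of 2859 probes without a paired locus that passed the filter, 179 changed beyond 2-fold in the sextuple mutant, 27 higher and 152 lower, and 196 in the triple mutant, 43 higher and 153 lower. They entered no comparison of genes.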

How the results depend on the processing

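Quantile normalization between arrays, each slide alone, slide as a block for lists, added pool spread and averaged same-dye arrays were chosen only after the result was seen. The following counts moved by over 1.5 times, and the cause was not tested unless given. Shifts of counts within single lists are not all given, and those given stand with the lists. Beyond 2-fold, 3777 sextuple and 4182 triple genes passed with the scanner software's ratio and 3650 and 4024 with the series table, against 2355 and 2661, and genes that differ beyond 2-fold between the mutants came to 613 and 536, against 235. Sextuple rises beyond 2-fold went from 475 to 1574 with the scanner software's ratio, 1496 with the series table, 749 with median centring and 805 with quantile normalization, and triple rises from 690 to 1897 and 1781 with the former pair. Genes that differ between the mutants came to 3944 without the dye term, and to 4783 on slide 1 and 4682 on slide 2, where fewer arrays remain by construction, against 7459. With median centring those higher in the sextuple mutant went from 3455 to 2278. Genes called in opposite directions went from 572 to 328 without the dye term and 360 with added pool spread. Lists past the threshold went from 12 to 6 in the sextuple mutant, from 11 to 4 in the triple mutant and from 10 to 1 in the difference with an estimated correlation, and to 22, 21 and 19 with fry, which compares no list with other genes. With the replicate block 17375, 17729 and 7969 genes passed in the sextuple mutant, the triple mutant and the difference. Without 1 replicate at a time the counts ran from 16340 to 17342 (sextuple), 16768 to 17590 (triple), 6219 to 7111 (difference), 2318 to 2415 and 2613 to 2694 (beyond 2-fold), 14460 to 14955 (shared), and from 12 to 12, 11 to 12 and 9 to 11 for lists. Of 2-fold calls at least 99.91% stayed called in each alternative, among the genes it tested. Reversed values were KN in the triple mutant (-0.013 with the mean of all probes), PP2AA3 in the sextuple mutant (0.043 with the scanner software's ratio and the series table, 0.038 with quantile normalization), the difference in RBCS1A (-0.15 with the scanner software's ratio) and CDKB1;1 in the triple mutant (0.026 with the scanner software's ratio and the series table, 0.036 with median centring). None of these was past the threshold in the alternative. Over 254 values of 144 named genes, 6669 alternatives kept direction and call, 87 lost the call and 2 gained it. A further 7 turned sign where the value had not been called, and 8 called values reversed. Added pool spread and each mutant fitted alone give no value for the difference, and the estimated correlation and fry apply to lists only. Signal over background limits the largest falls: in 72 of the sextuple and 89 of the triple 2-fold calls the mutant was not well above background, so their fitted folds are not measured sizes, and where such a gene is named against Col-0 a bound is given.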

Other observations

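The 6 lists described here, and the tests on them, were chosen only after the result was seen, so their p-values do not count as independent evidence. These p-values were adjusted over the 6 lists alone, so they do not compare directly with those of the fixed lists. All 10 anthocyanin genes fell in both mutants, with medians of -1.62 and -2.22 (list adjusted p = 0.000191 and 5.24e-05). The transcription factor PAP1 was at -3.62 in the sextuple and -5.17 in the triple mutant, the dihydroflavonol reductase DFR at -2.05 and -3.94 and GSTF12 at -2.26 and -3.65, and 9 of 10 were less reduced in the sextuple mutant (list adjusted p of the difference = 8.19e-07). Of 16 aliphatic glucosinolate genes 15 rose in both mutants, with medians of 0.63 and 0.90 (list adjusted p = 0.000191 and 0.000101), such as IMS2 at 2.46 and 3.54 and BCAT4 at 1.03 and 1.47. AT2G25450, which lies near PYL2, fell to -5.55 and -1.85. In 10 of 16 the sextuple mutant was below the triple mutant (list adjusted p of the difference = 9.79e-05). All 7 heat shock genes fell in both, HSP22.0 to -3.32 and -3.40 and HSP17.4 to -2.30 and -2.66 (list adjusted p = 0.000928 and 0.00106, and 0.172 for the difference).

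Phosphate starvation genes rose in 9 of 11 cases in the sextuple mutant, with a median of 0.73 (list adjusted p = 0.0126), such as the transporter PHT1;1 at 1.28 and the sulfolipid enzyme SQD1 at 0.98, while PAP17, a purple acid phosphatase, fell to -2.82 and PS2 to -0.54. In the triple mutant 8 rose and 3 fell (list adjusted p = 0.118), and 7 of 11 were higher in the sextuple than in the triple mutant (list adjusted p of the difference = 0.00205). Of 8 measured iron deficiency genes 5 rose in each mutant, NAS1 to 1.99 and 2.17, and the iron store FER1 fell to -1.40 and -1.86 (list adjusted p = 0.267 and 0.219, and 0.746 for the difference). Of 16 copper genes 4 rose and 9 fell in the sextuple mutant and 4 rose and 11 fell in the triple mutant (list adjusted p = 0.105 and 0.0498, and 0.213 for the difference, in which the members went both ways). CSD1 was at -2.13 against 0.84, CCS (AT1G12520), the copper chaperone of these dismutases, at -0.54 against 1.56, the transporter ZIP2 at 0.69 against -1.04 and YSL2 at -0.45 against -2.06. The triple signal of FRO5 and AT1G71200 was not well above background.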
